A study of Mus musculus with 19 samples.

How the data were processed

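Sorted GMPs, 10000 to 50000 cells per sample, were collected for RNA extraction and sequenced as TruSeq libraries, per the labels' protocols. The submitters' processing notes name HISAT2 2.0.6, Partek 6.6, R 3.0.2, DESeq2 without a version and the mouse genome build mm10, without saying what each did. The read counter, the gene annotation and any filter on low values are not given in the sources used here. The deposited table gives 1 signal per gene and library, a normalized read count: each library's values are whole multiples of 1 step, as when read counts are divided by a size factor. Between 99.88% and 100% of a library's values lay within 0.1 of a whole number of steps, and these whole numbers were taken as its reads. The reads recovered ranged from 3470603 to 23001479 per library with a median of 4762451. The reads carry no molecular identifiers as far as the labels say, so depth speaks of counting error only.

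The table held 12036 genes and 0 columns of other series. Of these, 11998 names matched a symbol or synonym of the reference, and 17 names were dates, as a spreadsheet makes of some symbols, and were left as they stood. Genes with a mean of at least 10 normalized reads over all libraries were tested (11404) and 632 were left out. Gene positions are from the GENCODE M21 annotation of GRCm38 (mm10).

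The design fixed before the data were examined foresaw edgeR for read counts and limma for any normalized unit, so limma was used. Values were taken as log2(value + 1), which understates fold changes of genes with few reads. A linear model with the 6 groups and the batch as terms was fitted to all 19 libraries with limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust moderation, and 10 comparisons were tested, 2-sided. P-values were adjusted by the Benjamini-Hochberg method within a comparison and genes under 0.05 were called. The 24 gene lists, also fixed before the data were examined, cover LPS responses, myeloid programmes, markers of other cells the sorting gate could hold, cell cycle, metabolism and stress; 23 had enough measured genes to be tested, by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry, adjusted over the lists of a comparison.

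The genes named for the comparisons were set by a rule fixed before the data were examined. It took the 8 largest rises and the 8 largest falls among called genes with the same sign in both batches, without unnamed gene models and without the genes of lowest mean. It added up to 4 members of each list with the smallest p, Ldlr and Nlrp3 (the latter not analysed here), and the genes of smallest p where few or no genes passed. The text names a part of these. Genes named for the difference between batches were picked by hand, outside that rule.

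The alternatives planned were no batch term, only the compared groups, batch 2 only, quantile normalization, no filter or only genes above the median mean, pseudocounts of 0.1 and 10, limma without trend or robust moderation, a log2 fold change of at least 1, each library left out in turn, and the other list tests. Alternatives chosen after the data were seen were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, models without the batch 1 libraries labelled CD>WD_LPS, batch 1 only, and a marker score of other cells as a covariate.

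Simulated data were drawn from the real means and depths, with the same mean share and spread of a gene in every library and no batch difference. The shares recovered below need not hold in the real data, where batches differed. The model was tested on these simulated data with 200 genes changed by known folds. It recovered 84% of 4-fold and 44.4% of 2-fold changes for LPS in chow (5 of 133 calls were false), 85% and 35% for LPS in HFD, 80% and 14% for LPS in switched mice, 88% and 43% for HFD against chow with PBS, 77.6% and 37.4% for HFD against chow with LPS, and 67.7% and 8.16% for the HFD interaction (12 of 87 calls were false).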

Results

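RNA sequencing measured gene expression in sorted granulocyte-monocyte progenitors (GMPs), the bone marrow cells that give rise to neutrophils and monocytes, from mice whose genotype label names the loss of both Ldlr and Nlrp3. Ldlr encodes the receptor that takes up low-density lipoprotein, and Nlrp3 encodes an inflammasome sensor. The 19 libraries crossed 3 diets with an injection into a vein of either PBS or 10 µg of LPS, the endotoxin of gram-negative bacteria, 6 hours before the tissue was taken. The groups were chow with PBS (CD_PBS, n = 4), chow with LPS (CD_LPS, n = 3), a diet labelled HFD with PBS (HFD_PBS, n = 4) and with LPS (HFD_LPS, n = 3), and a diet labelled CD>WD, chow and then Western diet by its label and called switched here, with PBS (CD>WD_PBS, n = 2) and with LPS (CD>WD_LPS, n = 3). The order of the switched diets was read from the sign in the label, which could be meant the other way round, and the labels do not say whether HFD and the Western diet are the same. Batch 1 held 9 libraries and batch 2 held 10, and every group had libraries in both. The labels speak of injected mice but do not say that each library came from its own mouse, so p-values measure the spread between these libraries.

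The reads behind the values of each library came to 6314997, 5638376, 23001479 and 8972683 in CD_PBS replicates 1 to 4 and to 4140239, 4571939 and 4512650 in CD_LPS replicates 1 to 3. They came to 5701137, 6920981, 4345322 and 4807216 in HFD_PBS replicates 1 to 4 and to 3470603, 4235893 and 7177760 in HFD_LPS replicates 1 to 3. The switched libraries had 4311492 and 19966106 reads in CD>WD_PBS replicates 1 and 2 and 3990682, 4762451 and 4341599 in CD>WD_LPS replicates 1 to 3. Of 12036 genes with values, 11404 with a mean of at least 10 normalized reads were tested.

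Ldlr, which lies on chromosome 9 from 21723483 to 21749919 on the plus strand (mm10), had reads in every library. Its normalized reads were 755, 420, 808 and 820 in CD_PBS replicates 1 to 4, 408, 588, 604 and 735 in HFD_PBS replicates 1 to 4, and 629 and 231 in CD>WD_PBS replicates 1 and 2. With LPS they were 959, 1913 and 1959 in CD_LPS, 890, 1355 and 697 in HFD_LPS, and 760, 668 and 1471 in CD>WD_LPS. The LPS difference of Ldlr was 1.11 ± 0.35 (log2, SE) in chow and 0.66 ± 0.35 in HFD, with adjusted p of 0.0821 and 0.338. The labels do not say which part of Ldlr was deleted and no library of another genotype was included, so these levels do not check the genotype label. Nlrp3 was not analysed here, so its part of the genotype label was not checked.

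At equal group, 5658 of the 11404 genes (49.6%) differed between the 9 libraries of batch 1 and the 10 of batch 2, 3108 of them higher in batch 2. Markers of other blood cells were higher in batch 2, by a median of 3.27 (log2) for late granule genes of maturing neutrophils, 3.87 for lymphoid genes, 3.10 for eosinophil, basophil and mast cell genes and 1.84 for erythroid and megakaryocyte genes. Each library pools sorted cells, so it does not show whether other cells or the GMPs themselves expressed these genes. Prss34, a basophil and mast cell protease, averaged 754 ± 1200 normalized reads (SD, n = 9) in batch 1 and 43100 ± 38600 (n = 10) in batch 2. S100a8, abundant in neutrophils, averaged 320 ± 266 and 2600 ± 1740, and the globin gene Hbb-bt 88.1 ± 113 and 3220 ± 2700. The primary granule genes Mpo and Elane went the other way, from 64900 ± 24100 to 37700 ± 26400 and from 9540 ± 5340 to 4260 ± 4600. All comparisons below carried a batch term.

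**Figure D1:**
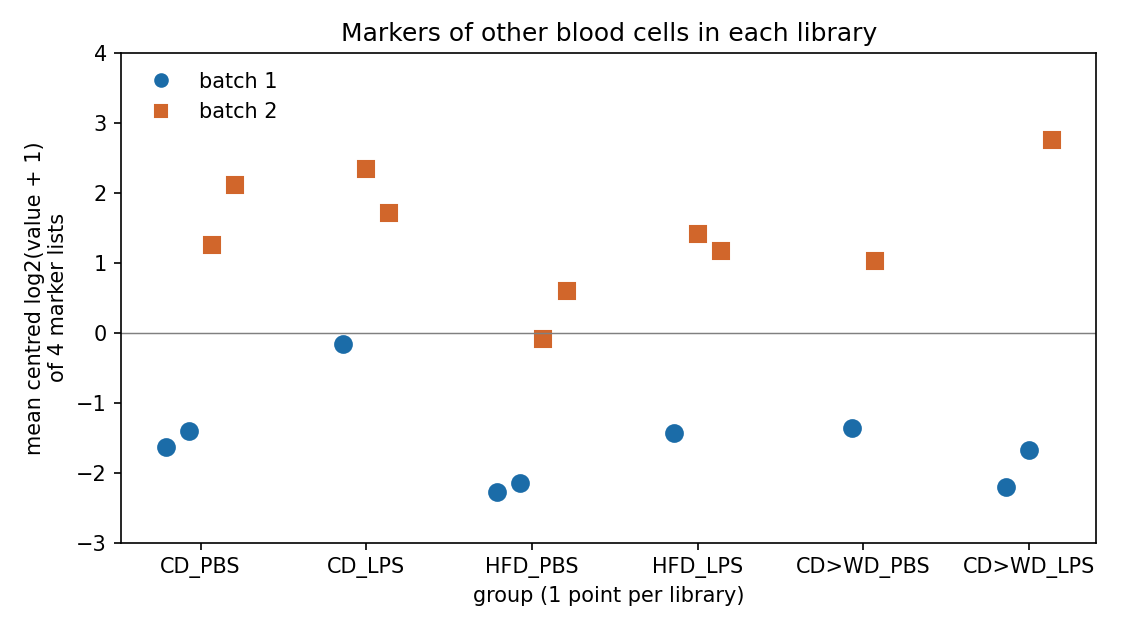
Mean centred log2(normalized reads + 1) of 4 marker lists for other blood cells (late granule, lymphoid, erythroid and megakaryocyte, and eosinophil, basophil and mast cell) on the vertical axis, with 1 point per library, grouped by diet and injection on the horizontal axis; circles are batch 1 and squares are batch 2. Scores ran from -2.28 to -0.17 in the 9 libraries of batch 1 and from -0.08 to 2.75 in the 10 libraries of batch 2.

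The first question was what LPS does to GMPs of mice on chow. Saa3, an acute-phase protein gene (chromosome 7, 46711998 to 46715700), went from 0.407 ± 0.49 normalized reads (SD, n = 4) with PBS to 739 ± 146 (n = 3) with LPS, a change of 9.02 ± 1.35 (log2, SE). Cxcl10, an interferon-induced chemokine gene (chromosome 5, 92346638 to 92348889), went from 2.2 ± 3.17 to 399 ± 17.7, a change of 7.20 ± 1.16. The immunity-related GTPase genes Iigp1 and Tgtp1 rose by 7.39 ± 1.16 and 6.32 ± 1.04, and Cxcl9 and Serpina3f by 5.95 ± 1.14 and 6.29 ± 0.95. The steepest falls included Kcnip3 (-3.88 ± 0.54), Ldhb, a lactate dehydrogenase subunit (-3.45 ± 0.39), Clec7a, the beta-glucan receptor Dectin-1 (-3.24 ± 0.56), and Cldn15, a tight junction protein (-2.95 ± 0.38).

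By gene group, 30 of the 31 type I interferon genes rose in chow (31 adjusted over the list alone), with a list median of 3.06 (2.96 in batch 1 and 3.45 in batch 2); Oas3, a sensor of double-stranded RNA, rose by 4.46 ± 0.59 and Usp18, which dampens interferon signalling, by 4.09 ± 0.57. Of the 28 genes for interferon-inducible GTPases and antigen presentation, 21 rose (22 adjusted over the list alone; median 2.91), among them Igtp (3.77 ± 0.50) and Gbp6 (5.60 ± 0.86). Of the 27 NF-kB and inflammatory genes, 13 rose (15 adjusted over the list alone; median 1.82), among them Nfkb2 (1.82 ± 0.24) and the adhesion molecule Icam1 (1.82 ± 0.26). The camera test with a preset correlation placed these 3 lists above other genes (adjusted p = 1.01e-34, 4.54e-22 and 9.41e-15), and with an estimated correlation each had an adjusted p = 0.106. The fry test, which asks whether a set's genes move on balance in 1 direction and does not compare them with other genes, gave adjusted p of 0.00128, 0.00306 and 0.00306. In the immediate early and heat shock list, which also responds to handling, 3 of 19 genes rose (8 adjusted over the list alone; adjusted p = 1e-06, and adjusted p = 0.106 with an estimated correlation), among them Hspa1b by 4.92 ± 0.77. Tgtp1 and Hspa1b each have a near-identical neighbouring copy, so their values are uncertain where reads could be split between copies.

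Some genes of the GMP's own granulocyte programme fell in chow with LPS. Of 12 primary granule genes, 3 fell (6 fell and 1 rose adjusted over the list alone): Prss57 (-2.33 ± 0.32), the myeloperoxidase gene Mpo (-1.83 ± 0.37) and the neutrophil elastase gene Elane (-3.09 ± 0.62). The list's camera adjusted p was 0.00023, with an adjusted p = 0.204 with an estimated correlation. Csf3r, the receptor for G-CSF, fell by 1.28 ± 0.24. Among 19 monocyte genes 4 fell and 1 rose (6 and 1 adjusted over the list alone): Ly86 and Ly6c2 changed by -2.07 ± 0.44 and -1.99 ± 0.49, and Fcgr1, an Fc receptor, by 2.39 ± 0.60. That list had an adjusted p = 0.0179, and an adjusted p = 0.646 with an estimated correlation. The inflammasome sensor genes Mefv and Nlrp1b changed by -2.43 ± 0.41 and -1.67 ± 0.39. Ly6a, the stem cell antigen Sca-1, rose by 3.94 ± 0.74. In batch 1 the marker score of other cells was -0.17 in CD_LPS against -1.63 and -1.41 in CD_PBS. In batch 2 it was 2.34 and 1.72 in CD_LPS against 1.25 and 2.11 in CD_PBS. A change within GMPs and a change in the mix of sorted cells cannot be told apart for the genes of this paragraph.

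Lists of markers of other cells and of proliferation had few or no single genes past the test in chow. The eosinophil, basophil and mast cell list had a median of 1.52 (2.79 in batch 1 and 0.07 in batch 2) with 0 of 14 genes past the test, and the erythroid and megakaryocyte list a median of 0.93 with 1 of 21 genes higher, Itga2b (1.69 ± 0.43), whose call was lost without any library but CD_LPS replicate 1. Their camera adjusted p were 0.0192 and 0.0121, and adjusted p = 0.651 and 0.689 with an estimated correlation. S phase genes had a median of -0.45 and oxidative phosphorylation genes -0.29, with 0 of 20 and 0 of 28 genes past the test, camera adjusted p of 7.03e-06 and 1.54e-05, and adjusted p = 0.645 and 0.646 with an estimated correlation.

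In all, limma placed 537 genes past an adjusted p of 0.05 between CD_LPS and CD_PBS, 278 higher and 259 lower, and over all genes the differences within the 2 batches had a correlation of 0.531. Leaving out CD_PBS replicates 1 to 4 in turn gave 313, 308, 222 and 242 genes, and leaving out CD_LPS replicates 1 to 3 gave 1214, 189 and 199. Of 48 named genes past the test, 28 stayed past it whichever library was left out; Mpo lost its call without CD_LPS replicate 2, Elane without CD_LPS replicate 2 or 3, Ly86 without CD_LPS replicate 3, Fcgr1 without CD_PBS replicate 1 or 3 or CD_LPS replicate 2 or 3, Nlrp1b without CD_PBS replicate 3 or 4 or CD_LPS replicate 2 or 3, and Ly6c2 without any library but CD_LPS replicate 1.

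**Figure D2:**
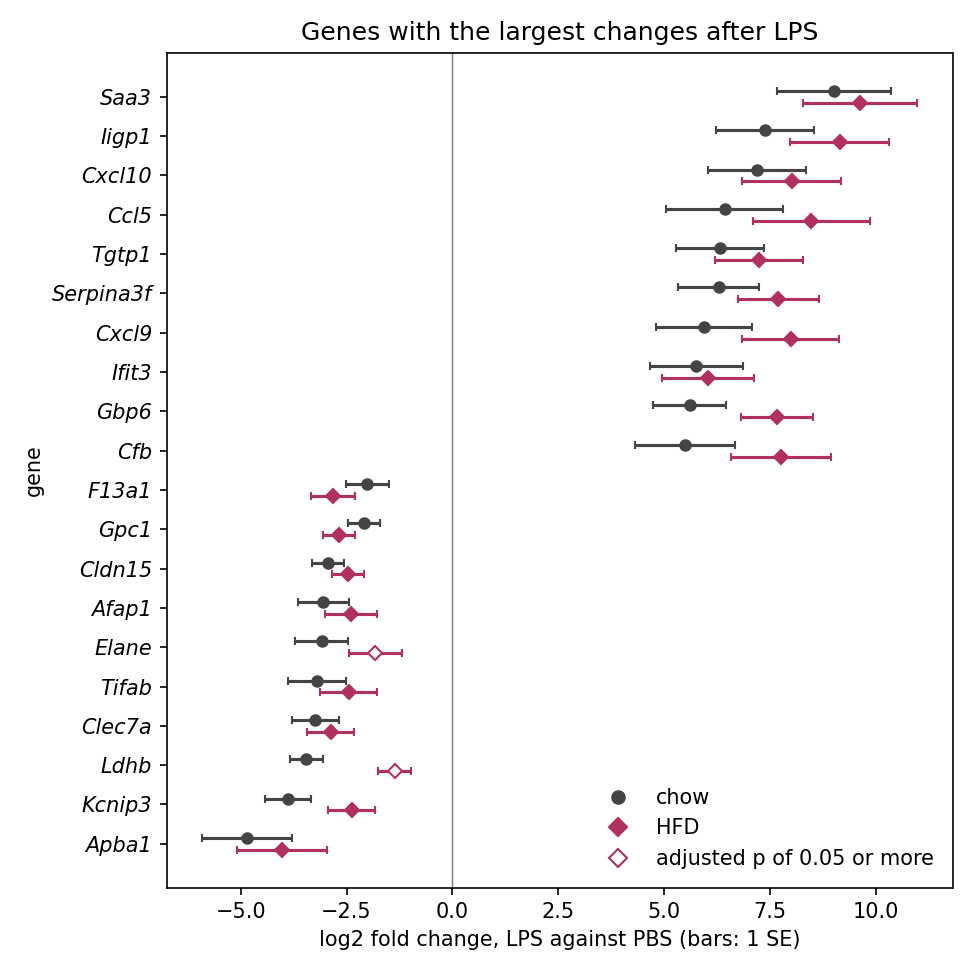
Log2 fold changes of LPS against PBS with SE (error bars) for named genes in chow (n = 3 against 4) and in HFD (n = 3 against 4); open markers are genes at an adjusted p of 0.05 or more in that diet. Saa3 lies at 9.02 in chow and 9.63 in HFD.

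The same question was asked of mice on HFD. Among the named genes Saa3 again had the largest rise, 9.63 ± 1.35 (log2, SE), from 1.15 ± 1.79 normalized reads (SD, n = 4) to 2670 ± 3480 (n = 3), a mean carried by unequal libraries. Iigp1 rose by 9.15 ± 1.16, Cxcl10 by 8.01 ± 1.16, the chemokine gene Ccl5 by 8.48 ± 1.38 and the complement factor B gene Cfb by 7.77 ± 1.18. Among the falls, F13a1, a coagulation factor subunit of monocytes, changed by -2.81 ± 0.51, the glypican gene Gpc1 by -2.68 ± 0.38, Clec7a by -2.87 ± 0.56 and Cldn15 by -2.46 ± 0.38.

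In HFD 29 of 31 type I interferon genes rose (31 adjusted over the list alone; median 3.10, 3.81 in batch 1 and 3.13 in batch 2), with Irf7, a master regulator of interferon genes, at 5.51 ± 0.73 and Isg15 at 5.61 ± 0.79. The GTPase and antigen presentation list had 21 of 28 genes higher (22 adjusted over the list alone), with Gbp6 at 7.67 ± 0.86 and Igtp at 4.31 ± 0.50. The NF-kB and inflammatory list had 14 of 27 higher (19 adjusted over the list alone), with Icam1 at 2.40 ± 0.26 and Nfkb2 at 1.65 ± 0.24. Camera adjusted p for these lists were 1.54e-38, 2.97e-28 and 1.07e-17, and each had an adjusted p = 0.0857 with an estimated correlation; fry gave 0.000963, 0.000963 and 0.00187. Prss57 was the 1 primary granule gene of 12 that fell (-1.85 ± 0.32; 7 fell and 2 rose adjusted over the list alone), in a list with an adjusted p = 0.0118, and adjusted p = 0.461 with an estimated correlation. Of 19 monocyte genes 4 fell and 1 rose (7 and 1 adjusted over the list alone), among them Zeb2, a transcription factor (-1.61 ± 0.26). That list's median was 0.58 in batch 1 and -0.64 in batch 2, with an adjusted p = 0.0273, and adjusted p = 0.753 with an estimated correlation. The marker score of other cells was -1.43 in HFD_LPS against -2.28 and -2.14 in HFD_PBS in batch 1. In batch 2 it was 1.41 and 1.17 in HFD_LPS against -0.08 and 0.60 in HFD_PBS. For the primary granule and monocyte genes, a change within GMPs and a change in the mix of sorted cells cannot be told apart.

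Among markers of eosinophils, basophils and mast cells, 2 of 14 rose with LPS in HFD (10 adjusted over the list alone; median 2.82): Il5ra by 3.66 ± 0.86 and Cpa3 by 2.21 ± 0.57, with a camera adjusted p = 1.4e-06, adjusted p = 0.334 with an estimated correlation and a fry adjusted p of 0.0453. Both calls were lost without HFD_LPS replicate 1, 2 or 3 or HFD_PBS replicate 4, and that of Cpa3 also without HFD_PBS replicate 3, at adjusted p of up to 0.113 and 0.248. In all 517 genes passed the test in limma, 319 higher and 198 lower, and the differences within the 2 batches had a correlation of 0.609 over all genes. Leaving out HFD_LPS replicates 1 to 3 gave 172, 298 and 326 genes, and leaving out HFD_PBS replicates 3 and 4 gave 280 and 310.

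The LPS comparisons of chow and HFD used different libraries but the same fitted model, with shared estimates of each gene's spread and batch difference. The comparisons are thus not fully independent. Of their higher genes 177 were shared, where independent lists would share 7.78, and of their lower genes 71 were shared, where independent lists would share 4.5. Across 11404 genes, which are not independent replicates, the fold changes had a Pearson correlation of 0.697 and a Spearman correlation of 0.407. The fold changes of the shared higher genes had a median of 2.27 in chow and 2.38 in HFD.

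In mice labelled with the switched diet, the LPS response was split between libraries. The score of the type I interferon list (mean centred log2) was 2.61 in CD>WD_LPS replicate 3, of batch 2, where the CD_LPS and HFD_LPS libraries of both batches lay between 1.63 and 2.61. It was -0.61 in replicate 1 and -1.71 in replicate 2, both of batch 1, where PBS libraries lay between -2.06 and -1.52. The list's median LPS difference was 0.20 in batch 1 and 3.32 in batch 2, that of the GTPase and antigen presentation list 0.10 and 3.13, and that of the NF-kB and inflammatory list 0.09 and 2.63. Irf7 differed by 1.23 in batch 1 and 6.24 in batch 2 (pooled 3.08 ± 0.87; adjusted p = 0.402), and Usp18 by 1.48 and 4.57 (pooled 2.61 ± 0.68; adjusted p = 0.317). Fcgr1 differed by 3.70 and 2.99 (pooled 3.24 ± 0.71; adjusted p = 0.241).

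**Figure D3:**
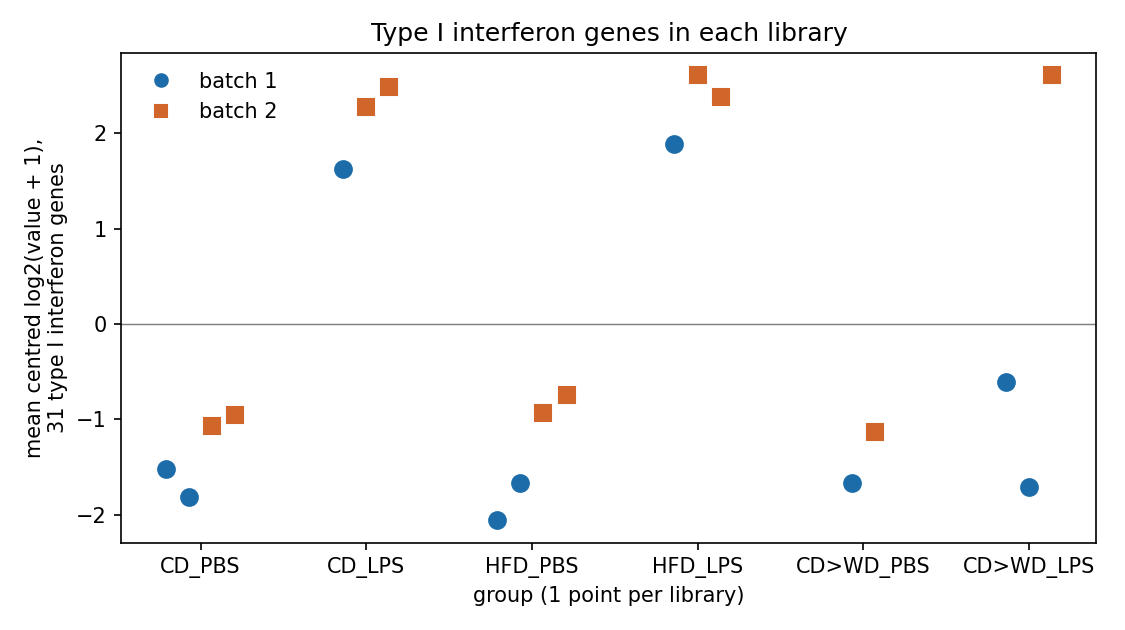
Mean centred log2(normalized reads + 1) of the 31 type I interferon genes on the vertical axis, with 1 point per library, grouped by diet and injection on the horizontal axis; circles are batch 1 and squares are batch 2. The LPS libraries of chow and HFD lie between 1.63 and 2.61, CD>WD_LPS replicates 1 and 2 at -0.61 and -1.71, and replicate 3 at 2.61.

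No single gene passed the test for LPS in switched mice: 0 genes in limma, with 1043 at an unadjusted p under 0.05, against 8 in edgeR and 91 in DESeq2. The smallest p belonged to Oas1g (2.83 ± 0.49), Mov10 (1.41 ± 0.27) and Rabggta (1.07 ± 0.21), each at an adjusted p of 0.23. Within batches 1 and 2 Oas1g differed by 2.64 and 3.38, Mov10 by 1.14 and 1.95 and Rabggta by 1.01 and 1.11. The batch 1 values average CD>WD_LPS replicates 1 and 2, so they do not show replicate 2 alone. Adjusted over the list alone, 14 of 31 interferon genes rose; the list's camera adjusted p was 5.1e-15, with an adjusted p = 0.623 with an estimated correlation. Of the 177 genes higher with LPS in both other diets, 176 were positive in the pooled fit of switched mice, with a median of 1.11. That fit averages unequal libraries. The mean of these genes (log2, above the chow and HFD PBS libraries of the same batch) was 0.73, 0.28 and 2.99 in CD>WD_LPS replicates 1 to 3. It lay between 2.79 and 3.16 in CD_LPS and HFD_LPS libraries and between -0.05 and 0.13 in batch 1 PBS libraries. Leaving out CD>WD_PBS replicate 1, CD>WD_PBS replicate 2 or CD>WD_LPS replicate 2 gave 65, 2 and 54 genes, and without both batch 1 CD>WD_LPS libraries 378 genes passed, where the lone remaining library was assumed to vary like the other groups.

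Without LPS, the question was what HFD does to resting GMPs. The genes with the smallest p were Oas1g, an interferon-induced RNA sensor (2.39 ± 0.38 log2, SE; n = 4 each; adjusted p = 0.106), and St6galnac3, a sialyltransferase (-2.01 ± 0.36; adjusted p = 0.178). The unnamed gene model 2510009E07Rik had -2.50 ± 0.48. No gene passed the test. Among enzymes of cholesterol synthesis, Dhcr24 differed by -0.60 ± 0.17, Lss by -0.85 ± 0.27 and Sc5d by -0.72 ± 0.23 (each at an adjusted p of 0.466). The cholesterol synthesis list of 21 genes had a median of -0.25, with 3 genes lower adjusted over the list alone, and LXR targets and lipid handling genes had a median of 0.36, with Srebf1, a regulator of fatty acid synthesis, at 0.77 ± 0.27 and the sterol exporter Abcg1 at 0.95 ± 0.44. Monocyte genes had a median of 0.54, with the M-CSF receptor gene Csf1r at 1.12 ± 0.36, Klf4 at 2.06 ± 0.71 and Irf8 at 1.24 ± 0.45. In batches 1 and 2 Csf1r differed by 0.40 and 1.83, Irf8 by 0.12 and 2.36, Klf4 by 1.99 and 2.13 and Srebf1 by 0.36 and 1.18.

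Lists of markers of other cells had negative medians for HFD against chow in resting GMPs, with 0 genes past the test, and 2 of them lay near 0 in batch 1. The late granule list had a median of -0.84 (-0.19 in batch 1 and -1.76 in batch 2), the erythroid and megakaryocyte list -1.08 (Hbb-bt -1.50 ± 0.60), the lymphoid list -1.42 and the eosinophil, basophil and mast cell list -1.34 (0.05 and -2.03). The erythroid and megakaryocyte score was -3.62 in HFD_PBS replicate 2, and -0.397, -0.281 and 1.09 in HFD_PBS replicates 1, 3 and 4. In CD_PBS replicates 1 to 4 that score was -0.683, -0.668, 0.363 and 1.44, so for this list the libraries of the diets overlapped. The marker score of other cells over the 4 lists did not overlap within a batch. It was -2.28 and -2.14 in HFD_PBS against -1.63 and -1.41 in CD_PBS in batch 1, and -0.08 and 0.60 against 1.25 and 2.11 in batch 2. A change within GMPs and a change in the mix of sorted cells cannot be told apart for HFD against chow with PBS. Camera adjusted p were 0.00149 for cholesterol synthesis, 0.00292 for LXR targets, 3.77e-05 for monocyte, 5.66e-05 for late granule, 0.000326 for erythroid, 0.00266 for lymphoid and 0.000402 for eosinophil, basophil and mast cell genes. In the same order the lists had adjusted p = 0.569, 0.347, 0.495, 0.569, 0.627, 0.495 and 0.569 with an estimated correlation. Between HFD and chow with PBS, 0 genes passed in limma, with 1031 at an unadjusted p under 0.05, against 26 in edgeR and 79 in DESeq2; 37 passed without HFD_PBS replicate 1 and 1 without CD_PBS replicate 1. The differences within batch 1 and within batch 2 had a correlation of 0.003 across genes.

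Resting GMPs of switched mice were compared with both other diets, with n = 2 switched libraries. Against chow, Vat1 (-0.92 ± 0.17; adjusted p = 0.59), Cebpe, a transcription factor of late granulocyte maturation (-1.60 ± 0.40; adjusted p = 1), and H2-Ke6 (-0.93 ± 0.23; adjusted p = 1) had the smallest p. The monocyte list had a median of 0.58, with Ctss at 1.02 ± 0.32, Csf1r at 0.98 ± 0.44 and Klf4 at 1.95 ± 0.87, and regulators of granulopoiesis had -0.42 (0.04 in batch 1 and -0.88 in batch 2). Their camera adjusted p were 3.48e-05 and 0.000341, and each had an adjusted p = 0.417 with an estimated correlation. For switched against chow, 0 genes passed in limma, with 423 at an unadjusted p under 0.05, against 5 in edgeR and 17 in DESeq2, and 2 passed without CD>WD_PBS replicate 1.

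Against HFD, the LXR target and lipid handling list of resting switched GMPs had a median of -0.33 with 0 genes past the test (camera adjusted p = 0.00441, and adjusted p = 0.27 with an estimated correlation). Srebf1 differed by -0.99 ± 0.33 (-0.18 in batch 1 and -1.80 in batch 2), Fasn, the fatty acid synthase, by -0.64 ± 0.23 (-0.09 and -1.18) and the desaturase Scd2 by -0.65 ± 0.30 (-0.79 and -0.52). Primary granule genes had a median of -0.65 and regulators of granulopoiesis -0.51, each with a camera adjusted p of 0.000267, and adjusted p = 0.276 and 0.27 with an estimated correlation. The granulopoiesis score was 0.035 in CD>WD_PBS replicate 1 and -1.12 in replicate 2. In HFD_PBS replicates 1 to 4 that score was -0.088, 0.409, 0.030 and -0.042, so the difference rested on CD>WD_PBS replicate 2. F2rl2 (2.10 ± 0.41), Oas1g (-2.31 ± 0.47) and Mfsd3 (-1.88 ± 0.38) had the smallest p, each at an adjusted p of 0.517. For switched against HFD with PBS, 0 genes passed in limma and 0 in edgeR, with 876 at an unadjusted p under 0.05, against 14 in DESeq2, and 93 passed without CD>WD_PBS replicate 1. No list of either switched comparison with PBS passed with an estimated correlation or by fry. Markers of other cells differed as well: their score was -1.36 in CD>WD_PBS against -2.28 and -2.14 in HFD_PBS in batch 1. In batch 2 it was 1.02 against -0.08 and 0.60.

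The next question was whether LPS leaves GMPs of HFD mice different from those of chow mice (n = 3 each). Ifi211, an interferon-inducible DNA sensor family gene (chromosome 1, 173896345 to 173913046), was higher in HFD, at 768 ± 367 normalized reads (SD) against 90.7 ± 14.9, a difference of 2.98 ± 0.58 (log2, SE; adjusted p = 0.0289). Ldhb, at 80.5 ± 34 against 14.8 ± 4, was higher by 2.32 ± 0.42. The inflammasome sensors Nlrp1b and Mefv were higher by 1.91 ± 0.41 and 1.85 ± 0.44, and the G-CSF receptor gene Csf3r by 1.29 ± 0.26. Cd7, a T and NK cell surface protein, was lower in HFD, at 56 ± 49.7 against 957 ± 813 (-4.31 ± 0.85). Btg2, an antiproliferative immediate early gene, and Arrdc4, an arrestin family gene, were lower by -2.08 ± 0.39 and -2.29 ± 0.46. Ldhb, Kcnip3, Mefv, Nlrp1b and Csf3r also fell with LPS in chow, in a comparison that used the same CD_LPS libraries, so the pairs of values are not independent.

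Among red cell markers 1 gene was lower in HFD with LPS: the erythroid and megakaryocyte list had a median of -1.94 (-3.90 in batch 1 and -1.12 in batch 2), with 1 of 21 genes past the test, the globin gene Hbb-bt at -2.54 ± 0.69. Hbb-b2 carried identical values, so reads of these near-identical globins cannot be assigned to either. Over the 4 marker lists for other cells, the score was -1.43, 1.41 and 1.17 in HFD_LPS replicates 1 to 3. It was -0.17, 2.34 and 1.72 in CD_LPS replicates 1 to 3, so it was lower in HFD in both batches. S phase genes had a median of 0.61, with 0 of 20 past the test and 13 higher adjusted over the list alone, oxidative phosphorylation genes 0.37 and monocyte genes 0.65. Histone and chromatin regulators had a median of -0.36, with 1 of 21 genes lower (3 adjusted over the list alone). Camera adjusted p were 2.97e-05 for erythroid, 2.41e-06 for S phase, 0.000117 for oxidative phosphorylation, 0.0259 for monocyte and 0.0301 for histone genes, and each list had an adjusted p = 0.848 with an estimated correlation.

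With LPS, limma placed 574 genes past the test between HFD and chow, 318 higher and 256 lower in HFD; edgeR gave 222 higher and 269 lower, and DESeq2 gave 779 higher and 939 lower. Over all genes the HFD minus chow differences of the 2 batches with LPS had a correlation of 0.109, with 1 library per diet in batch 1. The count of called genes was 0 without a batch term, 0 with the marker score of other cells as a covariate (median absolute log2 fold change 0.97 before and 0.836 after), and 0 without CD_LPS replicate 2 or 3 or any 1 of HFD_LPS replicates 1 to 3, and it was 2602 without CD_LPS replicate 1. None of the 27 named genes stayed past the test through every omission.

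Between switched and chow mice with LPS (n = 3 each), the difference of interferon genes was negative in batch 1 and near 0 in batch 2, and no gene passed the test. The interferon list had a median of -1.65 (-2.68 in batch 1 and 0.22 in batch 2), with 23 of 31 genes lower adjusted over the list alone and 0 over all genes. Stat1, the transcription factor of interferon signalling, had -1.99 ± 0.53 (-2.92 in batch 1 and -0.25 in batch 2; adjusted p = 0.315), Oas3 -2.40 ± 0.64 (-3.71 and -0.24; adjusted p = 0.315) and Irf7 -2.77 ± 0.79 (-4.68 and 0.16; adjusted p = 0.317). The GTPase and antigen presentation list had a median of -1.65 (-3.31 and 0.46), the NF-kB and inflammatory list -1.13 (-1.65 and 0.11) and the eosinophil, basophil and mast cell list -2.17 (-4.44 and -0.37). Camera adjusted p were 1.58e-16, 8.04e-12, 3.06e-08 and 1.21e-05, and each list had an adjusted p = 0.361 with an estimated correlation.

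Lenep (-3.04 ± 0.49), Lrmp (0.87 ± 0.15) and Ldhb (2.27 ± 0.42) had the smallest p for switched against chow with LPS, each at an adjusted p of 0.136. There, 0 genes passed in limma and 0 in edgeR, with 1289 at an unadjusted p under 0.05, against 38 in DESeq2. Without CD>WD_LPS replicate 3, the library of batch 2, 740 genes passed, and 5 passed without CD_LPS replicate 1.

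Whether diet changes the LPS response itself was tested by interaction. In the HFD interaction, Tsc22d3, a glucocorticoid-induced gene, had the smallest p (-2.21 ± 0.48), followed by Mmd (-1.10 ± 0.25) and Zfp783 (1.38 ± 0.32), each at an adjusted p of 0.568. For HFD, 0 genes passed in limma and 0 in edgeR, with 990 at an unadjusted p under 0.05, against 2 in DESeq2. For switched against chow, Ldhb (2.91 ± 0.61), Cldn15 (2.59 ± 0.59) and Lrmp (0.94 ± 0.22) had the smallest p, each at an adjusted p of 1. For the switched diet, 0 genes passed in limma and 0 in edgeR, with 295 at an unadjusted p under 0.05, against 4 in DESeq2 and 66 without CD>WD_LPS replicate 3. The interferon list's interaction had a median of -1.48 (-2.81 in batch 1 and 0.25 in batch 2), with a camera adjusted p of 2.4e-20, and an adjusted p = 0.229 with an estimated correlation.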

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

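The tests of the CD>WD_LPS libraries of batch 1, the test of a difference carried by batch 2 alone and the count of splits that keep the batch balance were chosen after the result was seen.

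Among 52 groups of 4 libraries examined for 1 value far from the other 3, 4 stood out. Chance picks about 1 in 20 groups of 4 draws from 1 normal population. Each group here held libraries of both batches, and the 52 groups reuse the same libraries, so that rate need not hold. Ldlr had 420 normalized reads in CD_PBS replicate 2 against 755 to 820 in the others. The score of the TLR and inflammasome list was -0.594 in HFD_PBS replicate 1 against 0.0743 to 0.117. The stem and multipotent progenitor list scored -1.18 in HFD_PBS replicate 2 against 0.193 to 0.269. The sex chromosome check list, of which only Xist was measured, scored 0.502 in HFD_PBS replicate 3 against -0.198 to -0.136.

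The interaction of diet and LPS passed for some lists by camera with a preset correlation, and for none with an estimated one or by fry. In the HFD interaction the erythroid and megakaryocyte list was lower (adjusted p = 0.0473) and the S phase list higher (adjusted p = 0.0113), and each had an adjusted p = 0.985 with an estimated correlation and 0.952 by fry. For switched against chow, the lists lower were type I interferon (adjusted p = 2.4e-20), GTPases and antigen presentation (4.11e-14), NF-kB and inflammatory (2.23e-06), eosinophil, basophil and mast cell (0.0124) and immediate early and heat shock (1.64e-05). Higher were primary granule (1.37e-06), granulopoiesis regulators (0.0295), oxidative phosphorylation (1.09e-05) and ribosomal protein genes (0.000173). The smallest adjusted p among these switched lists was 0.229 with an estimated correlation and 0.571 by fry. In batch 2 alone, with 1 CD>WD_LPS library, the medians were 0.25, 0.42, 0.99, 2.33 and 0.36 for the lists lower and -0.21 for oxidative phosphorylation, while primary granule, granulopoiesis and ribosomal protein genes stayed positive. Without both batch 1 CD>WD_LPS libraries the same medians turned, apart from that of immediate early and heat shock genes.

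The first pattern weighed is that CD>WD_LPS replicates 1 and 2, both of batch 1, lacked most of the LPS response. Processing of batch 1 as a whole is argued against, since the lower of the other batch 1 LPS libraries exceeded the batch 1 PBS mean of the interferon score by 3.38. Replicate 2 had 1.01% of the interferon response of the other batch 1 LPS libraries, 13.9% of the GTPase response and 12.5% of the NF-kB response, and its GTPase score lay 3.68 SD above the highest of the 5 batch 1 PBS libraries; replicate 1 had 32.5%, -2.66% and 9.1%, and its interferon score lay 4.46 SD above. No PBS library lay more than 1.81 SD above the others of its batch in these 3 lists, but over all genes replicate 2 lay 4.84 times sampling noise (median chi-square) from its nearest batch 1 PBS library, CD>WD_PBS replicate 1, within the 4.39 to 5.96 of the PBS libraries themselves, while replicate 1 lay at 11.3 and CD_LPS and HFD_LPS replicate 1 at 9.12 and 11.1. For replicate 1 the interferon list and the distance argue against a PBS label or a wholly missed injection. Its GTPase and NF-kB scores do not, at -2.26 and 0.641 SD above the highest batch 1 PBS library. It also had the fewest genes with a read of all libraries (11272) and the lowest eosinophil, basophil and mast cell score (-4.34). Its distance may thus have other sources than LPS, so the question is not settled for replicate 1 and stays open for replicate 2. A partly delivered injection and a weaker LPS response on the switched diet stay open and untested. In batch 2, CD>WD_LPS replicate 3 reached 105% of the interferon response of the other LPS libraries.

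The second pattern is the 574 genes that differed between HFD and chow with LPS. With the marker score of other cells as a covariate, the median absolute log2 fold change kept 86.2% (jackknife SE 19.1), going from 0.97 to 0.836 with all 574 signs kept, while the median SE went from 0.241 to 0.266 and no call was left. The bound of 80% was written before that result was seen, though the covariate was chosen after the data were seen. As written, the bound asked for no margin, and 86.2% met it, which by that rule counts against other cells. The bound lies within 1 jackknife SE of 86.2%, a margin that the written rule did not hold. With that margin, other cells and a diet effect cannot be told apart. Of 6217 genes called within batch 2, 59.1% had the same sign in batch 1, which had 1 library per diet, so a difference carried by batch 2 alone stays open; with 3 batch 1 libraries each that share was 68.4% for LPS in chow and 78% in HFD, and with 4 it was 46% for HFD against chow with PBS. A diet effect on the LPS response stays open, and the interaction itself called 0 genes in limma, with 990 at an unadjusted p under 0.05, 0 in edgeR and 2 in DESeq2.

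The third pattern is that markers of other blood cells were higher in batch 2. Read depth is argued against, since depths overlapped and marker scores of other cells did not (-2.28 to -0.17 in batch 1, -0.08 to 2.75 in batch 2). Batch 1 had 3470603 to 6920981 reads, a range that held HFD_LPS replicate 2 (4235893) and CD>WD_LPS replicate 3 (4341599) of batch 2. After every library was thinned to 3470603 reads, the median batch difference of 60 list genes kept 96.7% of its size (3.23 before and 3.12 after). Thinning leaves expected normalized values unchanged, so it weighs only the counting of genes with few reads. Mature neutrophils among the sorted cells are a candidate explanation, although a GMP gate would remove these cells. A separate list of 12 neutrophil genes was higher in batch 2 by a median of 2.63 with 11 positive. Ccl6 averaged 44.4 and 4130 normalized reads and Cxcr2 75.8 and 1360. Not all genes of the list moved: Trem1 differed by -0.29, Clec4e by 0.10 and Msrb1 by 0.11 (log2). Of the 12, 1 gene, Il1b, is in another list. Basophil-lineage, red cell and lymphoid markers rose as well (Mcpt8 437 and 20400), so neutrophils alone leave part open. The design gives no group that separates the batches, and no explanation apart from read depth and mature neutrophils was tested.

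Other splits of the same libraries were refitted to see how often they call as many genes. Over all splits, 1 of 35, the real one, reached 537 genes for LPS in chow (highest other 7). For LPS in HFD 1 of 35, the real one, reached 517 (highest other 199). Both shares lay under the bound of 0.05 written before. Only 18 of the 35 splits kept the real balance of batches. The others mix group with batch, so all 35 are not a fair reference. Among the 18 the real split alone reached its count in both diets (highest other 0 and 199). That share of 0.056 cannot fall under 0.05 with 18 splits, so chance is not excluded for either diet. For HFD against chow with LPS (real 574, highest other 1, 1 of 10 splits), the splits are too few for a share under 0.05. Where the real count is 0 every split reaches it, so the splits say nothing about chance for HFD against chow with PBS (35 of 35, highest other 0), switched against chow with LPS (10 of 10, highest other 2329) or the HFD interaction (100 of 100, highest other 1404). The split with 2329 genes set batch 1 against batch 2. The split with 1404 genes kept the real balance of batches, as did another with 1054 genes, and what set them apart was not tested.

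The number of lists called by camera with a preset correlation was matched by other splits. As many lists as the real 12 came from 6 of 35 splits for LPS in chow (highest other 13), as the real 9 from 17 of 35 for LPS in HFD (highest other 16), as the real 10 from 8 of 35 for HFD against chow with PBS (highest other 12), and as the real 2 from 95 of 100 for the HFD interaction (highest other 13), so chance cannot be excluded for these counts. For HFD against chow with LPS (8 of 10 splits, real 5, highest other 9) and switched against chow with LPS (3 of 10, real 11, highest other 12) the splits are too few for a share under 0.05.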

How the results depend on the processing

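The edgeR and DESeq2 fits, the models without CD>WD_LPS libraries of batch 1, batch 1 only and the other-cell covariate were chosen after the data were seen. No paired analysis was possible because the labels give no replicate numbers that groups share. Where an omission left 1 library in a group or batch, that library was assumed to vary like the other groups. The cause of each change below was not tested, apart from settings that leave out genes or libraries or ask for a larger fold. Of the alternative values of counts, 164 lay within 1.5 times the reported count and 80 did not; named genes kept direction and side of the threshold in 3125 values, lost the call in 575, gained it in 103 and turned direction in 13, and list medians or calls kept theirs in 236, lost them in 143 and turned in 20. Quantile normalization moved the median of all genes for LPS in switched mice by -0.102. Depth limits genes with few reads: 1 read stood for up to 1.73 normalized reads, in HFD_LPS replicate 1.

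For LPS in chow (537 genes), there were 221 without a batch term, 2444 with only the compared groups, 4387 in batch 2 only, 284 with genes above the median mean only, 979 in DESeq2, 1055 without both batch 1 CD>WD_LPS libraries, 43 in batch 1 only and 154 with the other-cell covariate, and omissions of 1 library gave 189 to 1214. For LPS in HFD (517), the same settings gave 248, 1451, 3169, 312, 950, 921, 68 and 182, and omissions 172 to 583. HFD against chow with LPS (574) had 0 without a batch term, 6217 in batch 2 only, 284 without trend or robust moderation, 274 at a log2 fold change of at least 1, 1718 in DESeq2, 1702 without both batch 1 CD>WD_LPS libraries, 0 in batch 1 only, with 1 library per diet, 0 with the covariate, where the median absolute log2 fold change went from 0.97 to 0.836 and all 574 signs were kept, and omissions 0 to 2602. With only the compared groups the split was 255 higher and 448 lower there.

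The spread in batch 2 only came from same-group pairs that differed by 2.61 to 4.4 times sampling noise (median chi-square), against 4.39 to 17.8 in batch 1, and the labels do not say that these libraries came from separate mice. The switched groups had 1 library each in batch 2, with no spread of their own. The comparisons with 0 genes gained calls as follows. LPS in switched mice had 4761 in batch 2 only, 8 in edgeR, 91 in DESeq2, 54 without CD>WD_LPS replicate 2, 378 without both, and 0 to 65 by omission. HFD against chow with PBS had 1 with only the compared groups, 4263 in batch 2 only, 26 in edgeR, 79 in DESeq2, 2 without CD>WD_LPS replicate 2 in the model, 5 without both, and 0 to 37 by omission. Switched against chow with PBS had 2811 in batch 2 only, 5 in edgeR, 17 in DESeq2 and 0 to 2 by omission, and switched against HFD 2000, 14 in DESeq2 and 0 to 93. Switched against chow with LPS had 154 in batch 2 only, 1 with a pseudocount of 0.1, 3 without trend or robust moderation, 38 in DESeq2, 1 without both batch 1 CD>WD_LPS libraries, 30 in batch 1 only and 0 to 740 by omission. The HFD interaction had 2191 in batch 2 only and 2 in DESeq2, and the switched interaction 495, 4 and 0 to 66 by omission. Of 85 list calls over the comparisons, 0 were made with an estimated correlation and 9 by fry.

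Some directions turned. Ldlr for HFD against chow with PBS was 0.06 with the covariate; for switched against chow with PBS it was 0.16 in batch 1 only and -1.85 to 0.20 by omission, and against HFD 0.36 and -1.60 to 0.44. Its HFD interaction was 0.093 in batch 1 only, and its switched interaction -0.021 in DESeq2, -0.59 in batch 1 only and -0.75 to 1.30 by omission. Irf7 for switched against chow with LPS was 0.16 in batch 2 only and 0.093 without both batch 1 CD>WD_LPS libraries. By the direction of camera, lists turned too, at medians as follows. In batch 1 only, the monocyte list for LPS in HFD had a median of 0.58, the oxidative phosphorylation list there -0.004, the eosinophil, basophil and mast cell list for HFD against chow with PBS 0.048, and the granulopoiesis list of the switched interaction -0.06. Without both batch 1 CD>WD_LPS libraries and in batch 2 only, medians for switched against chow with LPS were 0.19 and 0.22 (interferon), 0.35 and 0.46 (GTPases) and 0.16 and 0.11 (NF-kB). Those of the switched interaction were 0.18 and 0.25 (interferon), 0.36 and 0.42 (GTPases), 0.60 and 0.99 (NF-kB), 0.77 and 2.33 (eosinophil, basophil and mast cell) and -0.032 and -0.21 (oxidative phosphorylation).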

Other observations

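Further genes changed with LPS. Myd88, the adaptor of toll-like receptors, rose by 1.04 ± 0.21 (log2, SE) in chow and 0.92 ± 0.21 in HFD, and Casp4, the mouse caspase-11 that senses LPS in the cytosol, by 1.72 ± 0.35 and 1.96 ± 0.35. In chow the stress-response genes Ddit4 and Ppp1r15a rose by 2.45 ± 0.51 and 1.29 ± 0.32, while Pdk1, which restrains pyruvate oxidation, fell by 1.31 ± 0.26. In HFD, Lcn2, an iron-scavenging protein of neutrophils, rose by 3.25 ± 0.82, Csf2rb, the common beta chain of cytokine receptors, by 2.42 ± 0.55, the glucose transporter Slc2a1 by 1.04 ± 0.25 and Atf3 by 4.54 ± 1.02. Of these genes only Ddit4 in chow and Casp4 in HFD kept the call whichever library was left out. In HFD 1 of 20 glycolysis genes rose (2 adjusted over the list alone), with a camera adjusted p of 0.033 and an adjusted p = 0.635 with an estimated correlation.

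Further genes differed between HFD and chow with LPS. Tlr2 was higher in HFD by 1.42 ± 0.36, Gbp3 by 1.24 ± 0.30, Mpeg1, a pore-forming protein of phagocytes, by 1.81 ± 0.37, Maoa, a monoamine oxidase, by 1.95 ± 0.37, and the glycolysis genes Pdk1 and Gapdh by 1.16 ± 0.27 and 0.93 ± 0.23. Cebpa, a transcription factor required for GMPs to form, was lower (-0.98 ± 0.26), as were Kdm5b, a histone demethylase (-0.91 ± 0.23), and the water and glycerol channel Aqp9 (-2.96 ± 0.82). Each lost its call without any of CD_LPS replicates 2 and 3 and HFD_LPS replicates 1 to 3.

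The first principal component held 53.9% of the variance, and 36.7% after the batch difference was removed. No 2 libraries agreed within sampling noise. The closest pair by the median over genes of the chi-square of their reads was CD_LPS replicates 2 and 3, at 2.61 times the value sampling alone gives, followed by CD_PBS replicates 3 and 4 at 2.88 and HFD_PBS replicates 3 and 4 at 2.89. All these pairs were of batch 2. CD>WD_PBS replicate 1 and CD>WD_LPS replicate 2, of batch 1, differed by 4.84 times, the lowest value of any pair from different groups.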
